A study of Arabidopsis thaliana with 21 samples.

How the data were processed

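The series holds 21 RNA libraries of Arabidopsis thaliana, accession Col-0, in 7 groups of 3. Per the labels, total RNA was taken from stems and leaves, poly(A) RNA was selected, and strand-specific libraries were made and sequenced on an Illumina instrument. Plants grew under 16 h of light per day at 20 °C. The groups were read from the tissue and genotype labels, and the design text describes the 3 libraries of a group as biological replicates. Library titles carry no replicate number, so replicates were numbered in accession order and no library was paired with another.

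Per the submitters' processing notes, Trimmomatic 0.0.3, TopHat2 2.0.8 and the genome build TAIR10 were used. The notes give these without a role or an order. The way reads were assigned to genes, the strand setting and the read length are not given in the sources used here.

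The deposited file analysed here is the TAIR10 gene annotation, with 590264 lines of 9 columns. Its values are start and end positions of features in bp, counted from 1. The score column was tested on every line and held a value in 0 of them, and 0 columns belong to a library. Expression levels, depth per library and the precision that depth gives are therefore not analysed here. The 7 expression comparisons planned before the data were examined were not run. They were the comparison of genotypes in herbaceous stem, in cambium stem and in leaf, of cambium with herbaceous stem in each genotype, of wood with cambium stem in soc1-ful, and the interaction of genotype and stage. The parts of the plan that concern the annotation were carried out.

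Gene, transcript, exon, coding sequence and untranslated region (UTR) features were read with Python 3.11.15 and numpy 2.4.6, and tabulated with pandas 2.3.3. A gene's exonic bases are the union of exons over its isoforms, and its transcript length, exon number and introns are those of the first listed isoform. Exonic bases were counted as shared when at least 1 base lay in exons of 2 genes, separately for genes on the same strand and on opposite strands. Protein-coding genes were both the genes counted and the partners. A pair on opposite strands was called tail to tail when the 3′ ends overlapped and head to head when the 5′ ends did.

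The gene lists were fixed before the data were examined: 93 genes in 8 lists, looked up by locus identifier. The lists cover flowering and MADS-box genes, cambium regulators, secondary wall transcription factors, secondary wall polysaccharide genes, lignin genes, and markers of phloem, photosynthesis and epidermis. The rule for genes named in the text was also fixed then. It takes SOC1 and FUL in full and, per list, the members with the most isoforms, the longest gene, and every member that shares exonic bases with another gene. List genes with repeated words, the introns of the flowering list, and members that share bases in the TAIR10.1 annotation alone were named after their values were seen.

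The TAIR10.1 assembly with its newer annotation served as the reference. The lengths of chromosomes 1 to 5 and of the chloroplast were the same in both, and the mitochondrial sequence had 366924 bp in the deposited file and 367808 bp in TAIR10.1. The first listed isoform of 27165 of 27206 nuclear coding genes (99.8%) gave an intact reading frame when cut from the TAIR10.1 sequence at the TAIR10 positions. TAIR10.1 sequence was used with TAIR10 positions on the 5 nuclear chromosomes only. Of the 93 list symbols, 85 were found at the same locus in TAIR10.1. All coordinates printed are TAIR10 positions.

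Repeated words were all stretches of 50 bases inside single exons that occur again anywhere in the nuclear, chloroplast or mitochondrial sequence on either strand. Words across exon junctions were not counted. The longest intron of each list was compared with 100000 random lists of coding genes with an intron, matched on exon number with numbers above 15 pooled. This permutation test was two-sided and adjusted over 8 lists by the Benjamini-Hochberg method. It was repeated, unadjusted, for the 14 MADS-box members of the flowering list and for its 4 other members. A further test of the flowering introns is not reported here. The share of list members with shared exonic bases was compared with all other coding genes by Fisher's exact test, two-sided, with scipy 1.17.1 and the same adjustment. Both tests were chosen after the data were examined. Genes of one list can be related by descent, which neither test takes into account. Figures were drawn with matplotlib 3.10.9.

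Some of the steps were tested on simulated data. The counting of shared bases recovered all 1012 pairs among 200 simulated genes. All simulated genes lay on the same strand. The split by strand, the tail to tail and head to head calls and the placement in UTRs were therefore not simulated. The word search recovered all 806 repeated words of 50 bases in 50000 simulated bases. The longest intron test, with 5000 simulated genes, called 6 of 100 lists with no shift at a threshold of 0.05 and 94 of 100 lists whose values were multiplied by 3. Each simulated list had as many members as the list of secondary wall transcription factors. These rates therefore do not cover shorter lists, such as the marker lists.

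Alternatives fixed before the data were examined were at least 50 shared bases, whole gene spans, coding sequence only, partners of any class, coding genes with both UTRs only, and exons joined over isoforms for transcript length. Alternatives added afterwards were the TAIR10.1 annotation, introns over all isoforms, each flowering gene left out in turn, words of 100 bases, and list shares among coding genes with both UTRs or in TAIR10.1.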

Results

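The series profiled RNA from stems and leaves of Arabidopsis wild type (WT, Col-0) and of soc1-ful, plants mutant in SOC1 and FUL whose stems the submitters describe as woody. SOC1 and FUL are MADS-box transcription factors that promote the floral transition. WT was sampled as herbaceous stem, cambium stem and leaf, and soc1-ful as herbaceous stem, cambium stem, wood stem and leaf, with 3 biological replicates in each of the 7 groups. Of the 21 libraries, 15 were from stem and 6 from leaf, 9 from WT and 12 from soc1-ful. The question of the design is how transcript levels differ between the genotypes and between stem stages. The deposited file analysed here is the TAIR10 gene annotation, which holds no value for any library. Expression, depth and the 7 group comparisons are therefore not analysed here, and no statement below concerns a difference between samples. What follows describes the gene models of the annotation, with attention to genes of flowering, cambium and wood.

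SOC1 (AT2G45660) lies on chromosome 2 at 18807538 to 18811047, on the minus strand, and spans 3510 bp. Its single isoform has 8 exons and 1320 bp, of which 645 bp are coding, 414 bp 5′ UTR and 261 bp 3′ UTR. Exon 1 (18810657 to 18811047, 391 bp) lies wholly in the 5′ UTR. Intron 1 has 440 bp and intron 2, the longest, 1002 bp. FUL (AT5G60910) lies on chromosome 5 at 24502482 to 24506143, also on the minus strand, and spans 3662 bp. Both of its isoforms have 8 exons. The first listed isoform has 1113 bp, with 729 bp coding, 130 bp 5′ UTR and 254 bp 3′ UTR, and its intron 1 has 893 bp. The other isoform starts at an exon of 16 bp (24505301 to 24505316), which leaves an intron 1 of 365 bp. Neither gene shared exonic bases with another annotated gene, and neither held a word of 50 bases that occurs again in the genome.

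**Figure D1:**
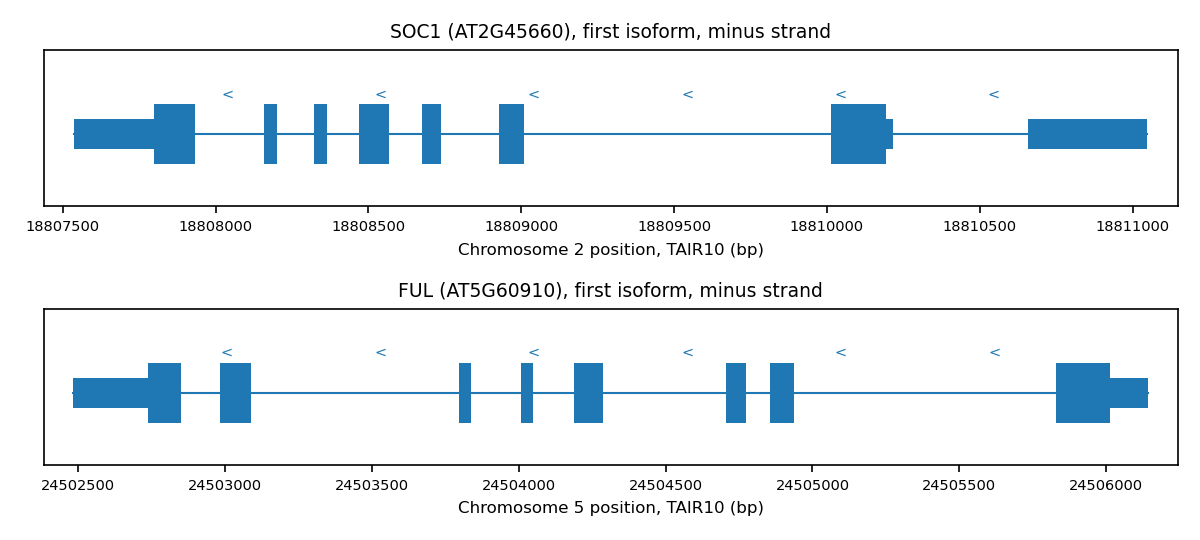
Gene models of SOC1 (top) and FUL (bottom), first listed isoform, against chromosome position in bp (TAIR10). Tall boxes are coding sequence, low boxes UTR and thin lines introns; both genes are on the minus strand, so the 5′ end is at the right, with the 1002 bp intron 2 of SOC1 and the 893 bp intron 1 of FUL.

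The annotation lists 33602 loci on 7 sequences. Protein-coding genes make up 27416 of them, transposable element genes 3903 and pseudogenes 924. The RNA genes comprise 689 for tRNA, 394 for other RNA, 177 for miRNA, 71 for snoRNA, 15 for rRNA and 13 for snRNA. The coding genes have 35386 transcripts, and 5804 genes (21.2%) have 2 or more isoforms, with at most 10. The median coding gene spans 1909 bp and has 4 exons and a transcript of 1327 bp. A single exon was annotated for 6141 coding genes (22.4%). UTRs were annotated at both ends of 19110 coding genes (69.7%) and at neither end of 6216 (22.7%).

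Of the 27416 coding genes, 3374 (12.3%) shared exonic bases with another coding gene. Sharing was mostly between strands, with 3022 genes (11.0%) overlapping a gene on the opposite strand and 385 (1.40%) a gene on the same strand. The median pair shared 84 bp. These counts depend on the annotation and the minimum overlap: in TAIR10.1, 6769 of 27562 coding genes (24.6%) shared bases with a coding gene, and with at least 50 shared bases the opposite-strand count in TAIR10 was 1990. Among the 1530 pairs on opposite strands, 1375 (89.9%) lay tail to tail, 85 (5.56%) head to head and 70 in another arrangement. Each base shared on opposite strands was placed once in each gene of its pair. Of these placements, 67.9% lay in a 3′ UTR, 27.1% in coding sequence and 5.52% in a 5′ UTR. A base can thus be 3′ UTR in 1 gene and coding in its partner, and it can fall in more than 1 kind across isoforms. Over both strands, 209 genes shared bases that were coding in both genes of the pair, 134 of them with a gene on the opposite strand. Reads from a pair on opposite strands can be assigned to a gene by strand, which the libraries keep per the labels, and reads from shared bases of a pair on the same strand cannot. The strand setting used for the reads is not given in the sources used here.

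Among the 93 list genes, 9 shared exonic bases with another coding gene, all on opposite strands and tail to tail, over 28 to 481 bp. All 9 belong to the secondary wall polysaccharide list (5 of 13) and the lignin list (4 of 18). In TAIR10, none of the 18 flowering genes, 16 cambium regulators, 16 secondary wall transcription factors, or 4 markers each of phloem, photosynthesis and epidermis did so. In TAIR10.1, 16 list genes shared bases with a coding gene. Among them were the cambium regulators RUL1, CYCD3;1 and CLE44, the secondary wall transcription factor VND6 and the photosynthesis marker RCA. Of these named genes, RCA shared the fewest bases, 3 bp (0.143% of its exonic bases), and CLE44 the most, 492 bp (33.5%). In the polysaccharide list 38.5% of members shared bases, against 12.3% (3369) of the 27403 other coding genes, an odds ratio of 4.46 (exact 95% interval 1.15 to 15.5). Fisher's exact test, two-sided, gave p = 0.0154, and 0.123 after adjustment over 8 lists, so the difference did not pass the threshold. In TAIR10.1 the share was 6 of 13 (46.2%) against 24.5% of the other coding genes, an odds ratio of 2.63 (exact 95% interval 0.731 to 9.16), with 0.377 as the adjusted p in Fisher's exact test. The lowest p of the 8 lists in TAIR10.1 was that of the flowering list, in the other direction. There 0 of 18 flowering genes shared bases, against 24.6% of the other coding genes (exact 95% interval of the odds ratio 0 to 0.698). Fisher's exact test gave p = 0.0110, and 0.0877 after adjustment, which did not pass. For the lignin list in TAIR10 the odds ratio was 2.04 (0.488 to 6.49), with p = 0.267 in Fisher's exact test and 0.427 after adjustment.

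The overlaps included all 3 cellulose synthases of the secondary wall. CESA4 (AT5G44030, chromosome 5, 17714645 to 17719723) shared 65 bp, 1.92% of its exonic bases, with AT5G44040. CESA7 (AT5G17420, chromosome 5, 5736630 to 5741465) shared 66 bp (1.96%) with AT5G17410. CESA8 (AT4G18780, chromosome 4, 10312624 to 10316790) shared 481 bp (14.8%) with AT4G18770, the transcription factor gene MYB98. The other list members were IRX8 (AT5G54690, chromosome 5, 22219224 to 22221840), a xylan gene that shared 51 bp (2.70%) with ILR3, and FLA11 (AT5G03170, chromosome 5, 752750 to 753657), which encodes a fasciclin-like arabinogalactan protein and shared 56 bp (6.17%) with P58IPK.

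**Figure D2:**
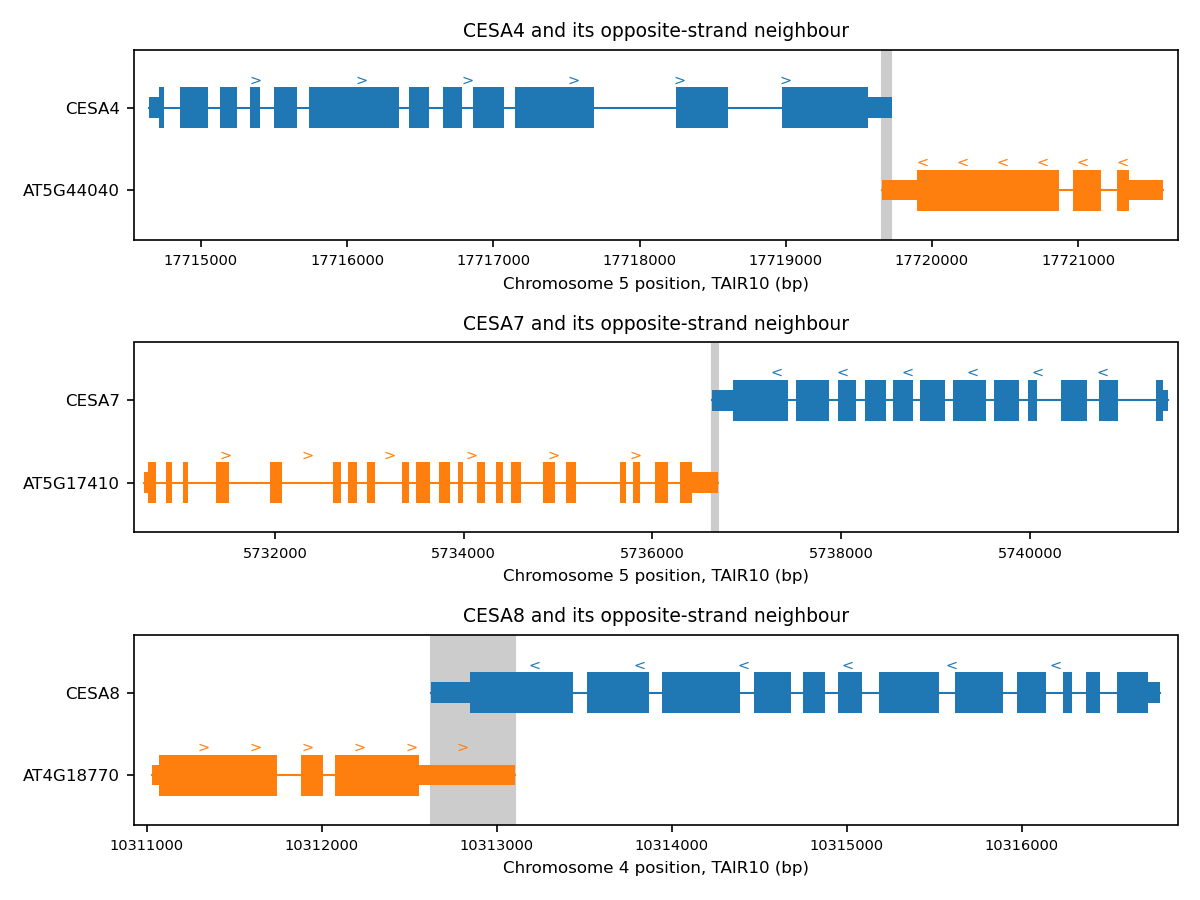
Gene models of CESA4, CESA7 and CESA8 (blue) and the neighbouring gene on the opposite strand (orange), first listed isoforms, against chromosome position in bp (TAIR10). Tall boxes are coding sequence, low boxes UTR, arrowheads the direction of transcription and grey the overlap of the gene spans, in which 65, 66 and 481 exonic bp are shared.

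In the lignin list, CCR1 (AT1G15950, chromosome 1, 5478754 to 5482180), which encodes cinnamoyl-CoA reductase, shared 473 bp with NRAMP6, 33.8% of its exonic bases and the highest share in the lists for a coding partner. C3H1 (AT2G40890, chromosome 2, 17058053 to 17060652), a hydroxylase of the monolignol pathway, shared 70 bp (3.71%) with CYSA. The laccase gene LAC11 (AT5G03260, chromosome 5, 777021 to 779424) shared 28 bp (1.45%) with AT5G03250. The peroxidase gene PRX64 (AT5G42180, chromosome 5, 16852630 to 16854224) shared 34 bp (2.77%) with AT5G42190. With partners of any class, 11 list genes shared bases. The additional ones were MYB58 (AT1G16490, chromosome 1, 5629655 to 5630995), a lignin regulator that shared 251 bp (21.3%) with the RNA gene AT1G16489, and the laccase gene LAC17 (AT5G60020, chromosome 5, 24167996 to 24170462), which shared 494 bp (24.1%) with the RNA gene AT5G60022. Both partners are on the opposite strand.

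More than 1 isoform was annotated for 17 of the 93 list genes. The flowering list accounts for 8 of these. AGL42 (AT5G62165, chromosome 5, 24964700 to 24968520), a relative of SOC1, had 5 isoforms, the most in any list, and FLC (AT5G10140, chromosome 5, 3173497 to 3179448), the floral repressor of the vernalization pathway, had 4 and the longest span of its list, 5952 bp. In TAIR10, all cambium regulators, secondary wall transcription factors and secondary wall polysaccharide genes had 1 isoform. Some members of each of these lists had more in TAIR10.1, at most 3, 2 and 5 in that order. The longest cambium regulator was the homeodomain gene HB8 (AT4G32880, chromosome 4, 15863452 to 15868625), with 5174 bp and 18 exons. KNAT7 (AT1G62990, chromosome 1, 23337365 to 23340688), also a homeodomain gene, was the longest secondary wall transcription factor at 3324 bp, and CESA4 the longest polysaccharide gene at 5079 bp. In the lignin list, 4 members had more than 1 isoform, with the most for the ligase gene 4CL1 (3 isoforms, AT1G51680, chromosome 1, 19158752 to 19161552), and PAL4 (AT3G10340, chromosome 3, 3204013 to 3208022) was the longest at 4010 bp. In the phloem list, APL (AT1G79430, chromosome 1, 29877228 to 29879206) was the one member with 2 isoforms and SEOR1 (AT3G01680, chromosome 3, 251981 to 255513) the longest at 3533 bp. RCA (AT2G39730, chromosome 2, 16570746 to 16573548), the Rubisco activase gene, had both the most isoforms (3) and the longest span (2803 bp) of the photosynthesis list. In the epidermis list, the wax gene CER1 (AT1G02205, chromosome 1, 418748 to 422438) had the most isoforms, 3, and the homeodomain gene ATML1 (AT4G21750, chromosome 4, 11555186 to 11560733) was the longest at 5548 bp.

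Median transcript length differed between the lists, from 1045.5 bp for flowering genes to 2237 bp for epidermis markers. It was 1100.5 bp for photosynthesis markers, 1183 bp for secondary wall transcription factors, 1547.5 bp for cambium regulators, 1623 bp for polysaccharide genes, 1742.5 bp for phloem markers and 1852 bp for lignin genes. These differences were not tested. The flowering list had the shortest median transcript and the longest median span, 3479 bp. The span was 3208 bp for epidermis markers, 2533.5 bp for the lignin genes and 1771.5 bp for the secondary wall transcription factors. Transcript lengths include annotated UTRs, in which the lists differed. Over all isoforms, both UTRs were annotated for 15 of 18 flowering genes and 13 of 16 cambium regulators. The same held for 11 of 16 secondary wall transcription factors and 3 of 4 phloem markers. Every member of the other lists had both. AGL71 (AT5G51870) is among the 15 flowering genes, although its first listed isoform, of 624 bp, has no UTR. How far UTR annotation shapes the ranking was not tested.

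The longest intron per gene had a median of 947.5 bp in the flowering list. Random lists of coding genes with the same exon numbers had a median of 300.5 bp, with the central 95% from 198.5 to 424 bp. The two-sided permutation p was 2.0e-05, the smallest the permutations can give, and 1.6e-04 after adjustment over 8 lists. FLC had the longest intron of the list, 3493 bp in intron 1, followed by AG (AT4G18960), a floral organ identity gene, with 2999 bp in intron 2. The shortest were 210 bp in TFL1 (AT5G03840) and 214 bp in FD (AT4G35900). The 14 MADS-box members had a median of 1028.5 bp, against 199 to 442.5 bp for the central 95% of their random lists (permutation p = 2.0e-05, unadjusted). The 4 other members had a median of 514.5 bp, within 107 to 623 bp of theirs (permutation p = 0.145, unadjusted), and fell into 2 pairs, with TFL1 and FD the shortest of the list and 815 bp in FT (AT1G65480) and 906 bp in LFY (AT5G61850). The difference between the MADS-box and the other members was not tested. Secondary wall transcription factors had a median of 426.5 bp against 228.5 bp in random lists (116 to 404 bp), with a permutation p of 0.0301 and 0.120 after adjustment, which did not pass. The adjusted permutation p was 0.144 for epidermis markers (median 576.5 bp), 0.272 for lignin genes (382.5 bp), 0.594 for phloem markers (211.5 bp) and 0.840 for cambium regulators (216 bp). It was 0.998 for both polysaccharide genes (286 bp) and photosynthesis markers (310 bp). Members without an intron were left out, so these values cover 10 of 13 polysaccharide genes, 2 of 4 photosynthesis markers and 14 of 16 cambium regulators. With such members counted as 0 bp, the medians were 99 bp, 68 bp and 194.5 bp. The test treats the members of a list as unrelated genes, which MADS-box genes are not.

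**Figure D3:**
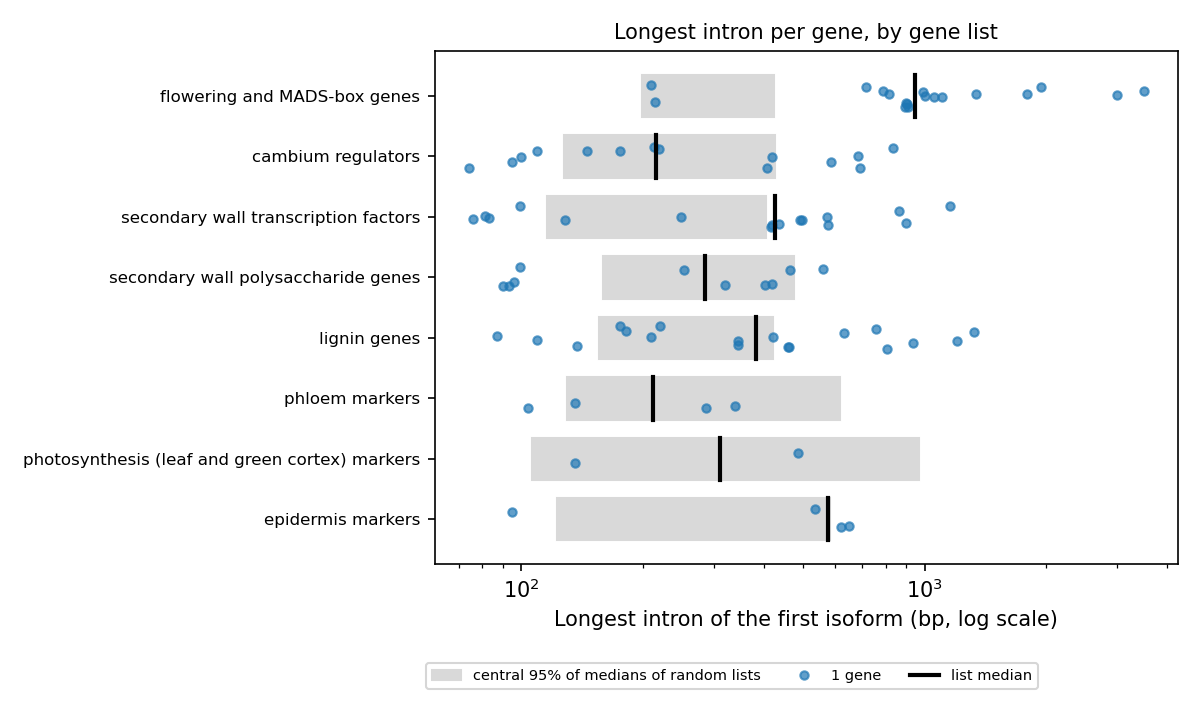
Longest intron of the first listed isoform in bp (log scale) for each list gene with an intron. Points are genes, with vertical scatter for visibility only, black bars list medians and grey boxes the central 95% of medians of 100000 random lists matched on exon number; the flowering median of 947.5 bp lies to the right of its box of 198.5 to 424 bp.

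Of 27206 nuclear coding genes, 23232 (85.4%) held no word of 50 exonic bases that occurs again in the genome, and in 481 (1.77%) more than 50% of words did. Of the 93 list genes, 5 held repeated words. LHCB1.1 (AT1G29920), which encodes a chlorophyll a/b binding protein, had 23.0% of its words repeated, with 176 matches in AT1G29930 and 100 in AT1G29910. PAL1 (AT2G37040) and PAL2 (AT3G53260), which encode phenylalanine ammonia-lyases, shared 31 words with each other, 1.27% and 1.28% of their words. AP1 (AT1G69120) and CAL (AT1G26310), a pair of related floral identity genes, shared 7 words, 0.824% and 1.06%. With words of 100 bases, LHCB1.1 alone of the 5 held repeated words (5.01%). The read length is not given in the sources used here, so which of these genes have reads with several matches is open.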

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

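The TAIR10.1 counts, introns over all isoforms, left-out genes, words of 100 bases and list shares among genes with both UTRs or in TAIR10.1 were chosen after the data were examined, and the other alternatives before. The count of coding genes sharing exonic bases stayed within 1.5 times of 3374 with at least 50 shared bases (2303), whole gene spans (3435) and partners of any class (3713). With at least 50 shared bases, the opposite-strand count was 1990 in place of 3022. In coding sequence only, 209 genes shared bases, 75 on the same strand and 134 on opposite strands, since UTRs were then left out. In the TAIR10.1 annotation, 6769 of 27562 coding genes (24.6%) shared bases with a coding gene, 947 on the same strand and 5939 on opposite strands. With partners of any class there, 7639 did, 1240 on the same strand and 6676 on opposite strands. The cause was not tested. TAIR10.1 gave more exonic bases than TAIR10 to 21519 of the 26719 nuclear coding genes found in both, with a median ratio of 1.095. Coding genes with both UTRs numbered 19110 of 27416. Joining exons over isoforms moved the median transcript length of 0 lists by more than 1.5 times. The median longest intron of the flowering list was 955 bp over all isoforms, 947.5 bp in TAIR10.1 and 907 to 988 bp with each gene left out, each at the smallest permutation p. With words of 100 bases, LHCB1.1 alone of the 5 list genes kept repeated words (5.01%). The planned expression comparisons and their alternatives (normalization, filter, test, pseudocount, replicates left out) were not run. No paired analysis was possible because no value per library was analysed. Depth, which would limit any expression result, is not analysed here.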

Other observations

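The counts in the TAIR10.1 annotation and the tests of both patterns were chosen after the annotation had been examined; the outcomes that would decide the intron tests were set down before those tests were run, and those of the wall list after. In the TAIR10.1 annotation, 19 of the 93 list genes shared exonic bases with a gene of any class, against 11 in the deposited TAIR10 annotation, and 87 had more exonic bases. FLC shared 804 bp, 68.1% of its exonic bases, with the long noncoding RNA gene AT5G01675 on the opposite strand, which has no counterpart among the FLC partners in TAIR10. CCR1 shared 1061 bp (54.2%) with the noncoding RNA gene AT1G05213 on the opposite strand, in addition to the 473 bp shared with NRAMP6. All 1335 exonic bp of MYB58 were covered by AT1G16489, which covered 251 bp in TAIR10, and LAC17 shared 506 bp (24.2%) with AT5G60022.

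Same-strand partners, whose reads strand cannot separate, appeared for 3 list genes in TAIR10.1 and for 0 in TAIR10. CLE44, a gene for a peptide signal of the cambium, shared 492 bp (33.5%) with AT4G13190, the D-type cyclin gene CYCD3;1 shared 40 bp (2.13%) with AT4G34150, and CESA4 shared 17 bp (0.451%) with AT5G44020. AGL42 had 17 isoforms in TAIR10.1 and 5 in TAIR10, and 26 list genes had more isoforms there.

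The longest introns of the flowering list had a median of 947.5 bp, above random lists of the same exon numbers (central 95% 198.5 to 424 bp), which argues against a higher exon number as the whole cause. The MADS-box members alone had 1028.5 bp, above their random lists, and the 4 other members 514.5 bp, within theirs. The annotation release is argued against by the median in TAIR10.1, also 947.5 bp (random lists 194 to 414.5 bp). Of 27206 nuclear coding loci, 26719 are found in both annotations, so a fault common to both would not show in this comparison. No biological explanation is reported here for this pattern.

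Shared exonic bases in 5 of 13 secondary wall polysaccharide genes were noticed among 8 lists. Noticing the highest of several lists could account for it, since the adjusted p in Fisher's exact test was 0.123. Better annotated UTRs in these genes remain open: all 13 have both UTRs, and among coding genes with both the odds ratio was 3.46, with an exact 95% interval of 0.889 to 11.99 that includes 1. No biological explanation was tested for this pattern.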
